A study of Danio rerio with 4 samples.

How the data were processed

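The series holds 4 single-cell RNA libraries from zebrafish (strain AB) heart ventricles, dissociated with collagenase and elastase and sorted for pdgfrb:EGFP cells, per the labels' protocols. Libraries were made with the 10x Genomics 3' kit v3.1, per the labels' protocols. The 6-month fish, wildtype and pdgfrb mutant, carried pdgfrb:EGFP, cxcl12b:Citrine and fli1a:DsRed, and the 18-month fish, uninjured or with the ventricle apex amputated 7 days before, carried pdgfrb:EGFP and cxcl12b:Citrine, per the labels. The nature of the mutation and the number of fish per library are not given in the sources used here.

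The deposited values are UMI counts per feature and barcode, whole numbers that the authors made with Cell Ranger 4.0.0, per the file headers, on GRCz11, per the submitters' processing notes. Those notes also name Seurat without saying for which step. The deposited matrices hold 25110 features, among them EGFP, Citrine and DsRedEx, and 1338, 1504, 5826 and 3127 barcodes for wildtype, mutant, uninjured and injured, each with at least 500 UMIs, per the files themselves. No class labels of the authors were used. Gene names are those the files pair with their feature IDs. Features that share a symbol were summed, which gave 24438 symbols, 518 of them from several IDs. The place of genes along chromosomes was taken from a RefSeq table of another assembly, GRCz12tu, for the order of neighbours alone, and 19141 of the 24438 symbols had a place there.

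Barcodes with at least 200 detected genes and at most 25% mitochondrial UMIs were kept. Scrublet, in scanpy 1.11.5, then marked 9 of 5471 barcodes (0.164%) as doublets, and these were left out. The number of doublets that remain was not estimated. This left 5462 cells. Counts were scaled to 10000 per cell and logged, 1987 of 2000 variable genes were used after leaving out reporters, pdgfrb, and mitochondrial, ribosomal protein and haemoglobin genes, and 30 principal components, a graph of 15 neighbours and Leiden clustering at resolution 1.0 (igraph 0.11.9) gave 17 clusters over the 4 libraries together, with no integration. Clusters were named from 11 marker lists fixed before the data were examined (124 of 129 symbols found). A cluster took the name of the list with the highest mean scaled level if at least 3 of its markers reached 0.25 of their top level and the mean was at least 0.2. Clusters with more leading genes (of 10) of another class stayed unnamed. A rule added after seeing the data also asked that 75% of the cluster's cells hold at least 2 UMIs of the list, and it left 1 cluster unnamed. Fibroblast-like and epicardium-like cells were also counted together, as fixed before.

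UMIs were summed over the cells of a class and given as CPM, scaled to the total UMIs of those cells. A log2 ratio is mutant over wildtype or injured over uninjured. With a count of 0 in 1 library the ratio was taken against a floor of 3 UMIs over the library's cells and is a bound. No ratio is given where both libraries are at or under 3. Intervals are at 95%. A gene counts as higher or lower if its ratio is beyond 1.5-fold and its interval excludes 1. This describes 2 libraries, not 2 conditions, since cells of 1 library are not replicates. There were 14 gene lists fixed before the data were examined (271 of 283 symbols found): mural, contractile, matrix, regeneration, cell cycle, PDGF, vessel signal, TGF-beta and BMP, inflammation, complement, dissociation stress, heat shock, glycolysis and interferon. The haemoglobin, ribosomal and mitochondrial lists were taken by symbol. Members with at least 20 UMIs over both libraries were measured. A list's median has an order-statistic interval and a percentile among 10000 random lists of the same size matched on mean expression.

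The rule for named genes, fixed before the data were examined, took genes with at least 50 UMIs over both libraries in all kept cells and in the 2 classes with most cells other than cardiomyocyte, erythrocyte and leukocyte classes (at least 50 cells in each library). It ranked them by the bound of the ratio's interval nearest to 1 and named the 5 highest and 5 lowest beyond 1.5-fold. Mitochondrial, ribosomal protein and haemoglobin genes were left out of that ranking. It also named pdgfrb, the reporters, cxcl12b, fli1a and the 2 to 4 members with most UMIs of each list described. At 6 months only fibroblast-like and epicardium-like cells met the class size, and at 18 months these and endocardium-like cells. Genes named outside the rule are said to be chosen after their values were seen.

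The ratio and list steps were tested on simulated data, Poisson counts for the real genes with 200 changed genes. In the mutant comparison 90.0% of genes changed 2-fold were called over all kept cells (3779 genes) and 92.0% in fibroblast-like and epicardium-like cells (1016 genes). In the injury comparison these shares were 96.0% (8687 genes), 90.0% (4236 genes) and 88.0% in endocardium-like cells (3536 genes). Of genes changed 1.5-fold, 50.0%, 26.0%, 34.0%, 50.0% and 44.0% were called in the same order. Intervals held the true value for 95.1 to 95.9% of genes, and 1.74 to 3.55% of unchanged genes were called. The simulated counts follow the Poisson model that the intervals assume, so coverage near 95% was fixed in advance. Real UMIs can clump in single cells, so these shares do not give the coverage or false calls in the real data.

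Alternatives were 100 or 400 genes as the minimum, no mitochondrial filter, doublets kept, resolutions 0.5 and 2.0, each pair of libraries clustered alone, every cell thinned to 500 UMIs, edgeR 4.0.16 TMM factors and DESeq2 1.42.0 size factors in R 4.3.3, totals without mitochondrial, ribosomal protein and haemoglobin genes, means over cells, and list minimums of 5 and 50 UMIs. After seeing the data, more were added: the highest 5% of doublet scores left out, clustering without the mural markers, shares without cardiomyocyte-like and erythrocyte-like cells, each cluster of the pooled class alone, the mural list over all kept cells, and every gene without the cell that holds most of its UMIs in each library. The planned median of the mural list in mural-like cells could not be computed, since the mutant library has no such cells. The 6-month and 18-month libraries were not compared with each other, because age and transgenes differ together. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.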

Results

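Single-cell RNA libraries were made from zebrafish heart ventricles after sorting for EGFP driven by pdgfrb, the gene of the platelet-derived growth factor receptor that mural cells (pericytes and vascular smooth muscle cells) and some fibroblasts and epicardial cells express. There were 4 libraries, 1 per group: wildtype and pdgfrb mutant fish of 6 months, and uninjured fish and fish 7 days after amputation of the ventricle's apex, both of 18 months. After filtering, the wildtype library held 947 cells and 1983524 UMIs (unique molecular identifiers). The mutant library held 1119 cells and 2772269 UMIs, the uninjured library 2003 cells and 7912205 UMIs, and the injured library 1393 cells and 6696081 UMIs. Median UMIs per cell were 1729, 2160, 3313 and 3645 in that order. With 1 library per group there is no replicate check of any difference given here, and no p-value is given. The exact intervals (Clopper-Pearson for shares, Poisson for UMIs, conditional binomial for ratios) and the limits that a count of 0 allows cover counting error only.

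Classes carry the ending "-like" because they were named from marker genes, not from labels. Cardiomyocyte-like cells made up 73.9% of wildtype, 83.0% of mutant, 52.8% of uninjured and 47.6% of injured cells. At 18 months, EGFP UMIs were present in 0.851% and 0.603% of these cells (median depths 2709 and 2988 UMIs), against 94.7% and 94.1% of mural-like cells (1327 and 1350 UMIs). Endocardium-like cells (endothelium and endocardium together) numbered 6 and 6 in the 6-month libraries and 350 and 246 in the 18-month libraries. A small cluster met the fixed marker rule for endothelium and endocardium but not the rule on own UMIs added after seeing the data, so it stayed unnamed. It held 0.528%, 0.357%, 1.55% and 2.30% of the cells.

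**Figure D1:**
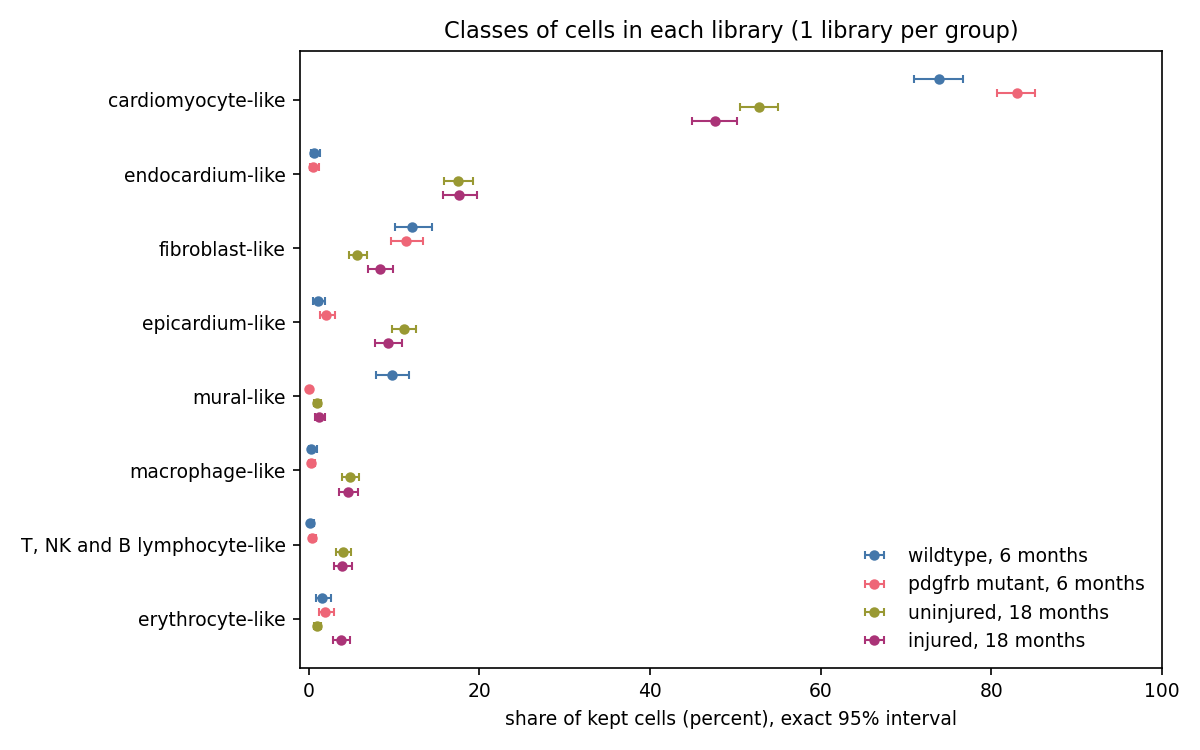
Share of kept cells (percent) in each class and library, with exact 95% intervals. Mural-like cells are 9.71% of the wildtype library and 0 of 1119 cells of the mutant library, and fibroblast-like cells are 12.1% and 11.4%.

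The first comparison asks how the sorted ventricle cells differ when pdgfrb is mutated. Mural-like cells made up 9.71% of the wildtype library (92 of 947 cells, 7.90 to 11.8%) and were not found in the mutant library (0 of 1119 cells, which allows a share of up to 0.268% at 3 counts, with an exact upper bound of 0.329%). Fibroblast-like and epicardium-like cells together held nearly the same share in both, 13.2% (125 cells) in wildtype and 13.5% (151 cells) in the mutant, a difference within counting error. The same cluster was the fibroblast-like class in both libraries (115 and 128 cells), as was the epicardium-like cluster (10 and 23 cells, but 3 and 1 when doublets were kept before clustering). The epicardium-like class held 18 and 35 cells at resolution 2.0 and 15 and 31 when thinned. There was no such class at resolution 0.5 or with the 6-month pair clustered alone. Counted without cardiomyocyte-like and erythrocyte-like cells, a denominator chosen after seeing the data, mural-like cells were 39.7% of 232 wildtype cells and 0 of 168 mutant cells, and fibroblast-like and epicardium-like cells 53.9% and 89.9%.

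Transcripts of pdgfrb itself (ENSDARG00000100897) numbered 115 in wildtype and 7 in the mutant, 58.0 and 2.52 CPM, UMIs scaled to the total of the cells summed (log2 ratio -4.52, 95% interval -5.87 to -3.43). The gene was also lower within fibroblast-like and epicardium-like cells, with 32 UMIs in wildtype and 7 in the mutant (-2.72, -4.15 to -1.52). In cardiomyocyte-like cells it was 0 in both libraries. The counted tag lies at the 3' end and the nature of the mutation is not given, so whether these values reflect the mutation cannot be told.

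EGFP was 520.3 CPM in wildtype and 92.0 in the mutant over all kept cells (-2.50, -2.70 to -2.30), and 631 CPM in both libraries in fibroblast-like and epicardium-like cells (0.00, -0.30 to 0.30). The chemokine gene cxcl12b had 70 UMIs in wildtype, every one of them in mural-like cells, and 4 in the mutant (-4.61, -6.53 to -3.19). Citrine, driven by cxcl12b, had 27 and 52 UMIs, a difference within counting error (0.46, -0.23 to 1.19). The DsRedEx feature had 0 UMIs in all 4 libraries, and fli1a, the endothelial gene whose promoter drives DsRed, had 4 and 3.

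Of the 15 measured members of the mural list, 13 were lower and 0 higher in the mutant over all kept cells, and the median log2 ratio was -2.74 (-3.90 to -2.03), below all 10000 random lists matched on expression. The list also named the mural-like class, so this largely restates the 0 mutant cells of that class and is not separate support. The 4 members with most UMIs were rgs5b, a regulator of G protein signalling (6.75-fold lower, log2 ratio -2.76), kcne4, a potassium channel subunit (15.5-fold lower, -3.95), and the myosin light chains myl9b (0.23) and myl9a (0.26), which were not lower. The 5 genes that ranked lowest were all highest in wildtype mural-like cells. They were atp1a1b, a sodium pump subunit (1 against 152 UMIs, -7.73), ndufa4l2a, a relative of a respiratory chain subunit (0 against 77, at least 35.9-fold lower), pcdh18a, a protocadherin (0 against 64, at least 29.8-fold lower), plp1b, a proteolipid protein (1 against 77, -6.75), and atp1b4, a relative of sodium pump beta subunits (0 against 50, at least 23.3-fold lower). The contractile list (7 of 11 lower) had a median of -1.64 and the PDGF list (2 of 3 lower) a median of -1.75. Both share members with the mural list. Within fibroblast-like and epicardium-like cells, with TMM scaling, 3 of 9 members of the mural list were higher and 2 lower (median 0.72). The contractile list there had 0 of 6 higher or lower (0.31), and the PDGF list 2 of 3 lower (-1.14).

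Of the 5 genes ranked highest in the mutant library, 3 lay in 8 cells or fewer: g0s2, an inhibitor of fat breakdown (92 UMIs in 1 cell), sla2, an adaptor of lymphocyte receptors (52 UMIs in 4 cells, 0 in wildtype) and her4.1, a Notch target (52 UMIs in 8 cells, 3 in wildtype). The others were the uncharacterised zgc:152791 (71 UMIs in 38 cells, 3 in wildtype) and cyp24a1, which inactivates vitamin D (66 UMIs in 31 cells, 5 in wildtype, log2 ratio 3.24). In the vessel signal list 2 members were higher and 7 lower of 14 (median -0.88, -2.03 to 0.05): the chemokine gene cxcl12a was higher (1.94, 1.70 to 2.19) and her6, a Notch target, lower (-1.45). Erythrocyte markers were higher for 7 of 8 members (median 1.84). In CPM, hbba1 was 2.56-fold and hbaa1 5.85-fold higher, globin genes with near copies that share reads. Erythrocyte-like cells were 1.58% of the wildtype and 1.97% of the mutant library.

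Within fibroblast-like and epicardium-like cells, cxcl12a, a chemokine that guides vessel growth, was 3.79-fold higher in the mutant (848 against 155 UMIs, in 99 and 44 cells, log2 ratio 1.92, 1.67 to 2.18). Also ranked highest were ifitm1, an interferon-induced membrane protein gene (1165 against 207 UMIs, 1.96), cyp24a1 (65 against 5, 3.17), rbp2a, a retinol carrier (113 UMIs in 3 cells, 0 in wildtype), and g0s2 (92 UMIs in 1 cell). Ranked lowest were the MAP kinase phosphatase genes dusp5 (7 against 50 UMIs, -3.37) and dusp2 (49 against 181, -2.41), the uncharacterised si:ch211-195m9.3 (16 against 82, -2.89) and si:ch73-335l21.4 (289 against 792, -1.98), and mb, myoglobin (60 against 221, -2.41), of which 1 wildtype cell held 177 UMIs. Without the top cells mb had a log2 ratio of -0.94.

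Of the matrix list, 12 of 15 members were lower in these mutant cells (median -0.75, -0.85 to -0.59, at percentile 0.59 of random lists), and 3 of 15 with TMM scaling. Examples are sparc, a collagen-binding protein gene (-0.67, with TMM -0.36), and the collagen I genes col1a2 (-0.59, -0.28), col1a1b (-0.62, -0.31) and col1a1a (-0.77, -0.46), none of which was beyond 1.5-fold with TMM. In the regeneration list 6 of 14 were lower (median -0.75, -1.21 to -0.07), among them hapln1a, which links hyaluronan to proteoglycans (-1.12), while fn1b, fibronectin, differed within counting error (-0.13, and 0.18 with TMM scaling). Dissociation stress genes, the immediate early genes that tissue digestion induces, were lower too: 14 of 20 in these cells (median -1.01, -1.25 to -0.64, at percentile 0), with fosab at -0.95, junba at -1.10, while jun (-0.52, with TMM -0.21) was under 1.5-fold. Over all kept cells 20 of 22 were lower (-1.23), with fosab at -1.32 and jun at -0.82. In cardiomyocyte-like cells, 83.0% of the mutant library, 1 member was higher and 3 lower of 17 with TMM (median 0.06). Ribosomal protein genes had a median of 0.45 in fibroblast-like and epicardium-like cells and 0.19 over all kept cells.

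Other lists moved in mutant fibroblast-like and epicardium-like cells as well. Fibroblast markers were lower for 10 of 12 members (median -0.70, with TMM 2 of 12), the glycolysis list for 8 of 11 (-0.91, with TMM 4 of 11) and the heat shock list for 7 of 13 (-0.80, with TMM 4 lower and 2 higher). Most fibroblast markers are also members of the matrix list and served to name these cells, so their count is not separate support. Cardiomyocyte markers were lower for 6 of 6, with TMM too, but had a median of -0.02 without the top cells. Epicardium markers had 1 higher and 1 lower of 6 (0.33, with TMM 4 higher and 1 lower, 0.64), and of 12 mitochondrial genes 1 was higher (0.37, with TMM 7, 0.67). In the fibroblast-like cluster alone, a split chosen after seeing the data, 4 of 14 regeneration genes were lower and 1 higher (with TMM 2 lower and 1 higher), and 8 of 15 matrix genes were lower (with TMM 2). In the epicardium-like cluster alone, with 23 mutant and 10 wildtype cells, 8 of 12 matrix genes (with TMM 7, median -0.86), 9 of 14 dissociation stress genes (with TMM 9) and 2 of 6 regeneration genes were lower. This class was smaller or absent under most other clusterings, so these counts hold for the main clustering only.

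Mitochondrial, ribosomal protein and haemoglobin genes were left out of the median log2 ratio of genes with at least 50 UMIs. It was -0.15 over all kept cells and -0.27 in fibroblast-like and epicardium-like cells, and TMM scaling adds 0.19 and 0.30. With it, 3 rather than 12 of 15 matrix genes, 5 rather than 6 of 14 regeneration genes (with 1 higher) and 11 rather than 14 of 20 dissociation stress genes (with 1 higher) were lower in these cells, and the medians became -0.44, -0.45 and -0.71. Of 80 ribosomal protein genes, 74 were higher instead of 5. Over all kept cells 7 of 15 matrix genes stayed lower, the inflammation list had 3 higher and 3 lower, the TGF-beta and BMP list 1 lower, the cell cycle list 1 higher and 2 lower, and the complement list 2 higher.

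Over all kept cells of this comparison, the heat shock list had 9 of 15 members lower (median -0.95), the matrix list 11 of 15 (-0.74), the regeneration list 9 of 14 (-0.96) and the glycolysis list 8 of 17 (-0.54). The inflammation list had 3 higher and 5 lower of 15 (-0.54), the TGF-beta and BMP list 3 lower of 6 (-0.59), and the cell cycle list 2 lower of 6 (-0.50). The complement list had 1 higher of 5 (0.20), and the interferon list 1 higher and 1 lower of 3 (0.33). The mitochondrial list differed little over all kept cells (0.06), and the haemoglobin list was higher for 4 of 4 (4.10). Sums over all kept cells mix classes whose shares differ, such as mural-like cells, found in wildtype alone. In cardiomyocyte-like cells the heat shock list had 3 higher and 3 lower of 14 with TMM (0.21).

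**Figure D2:**
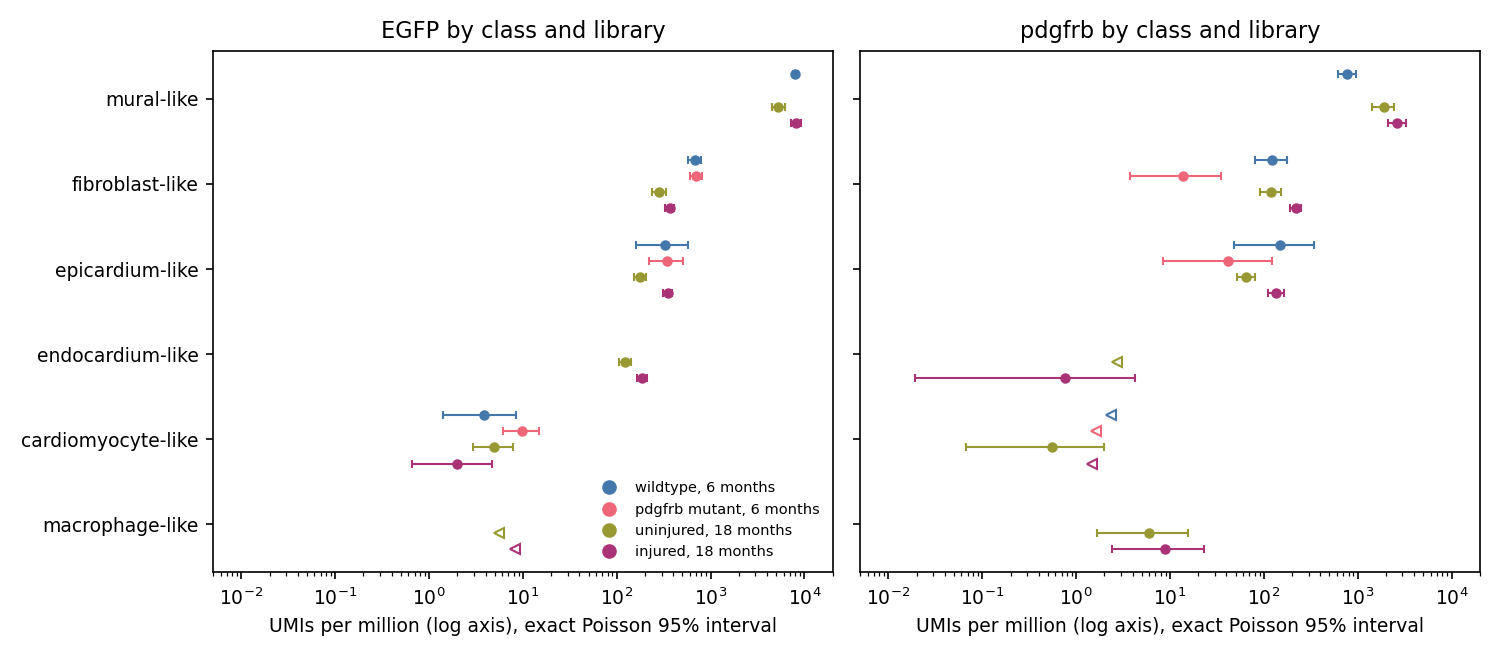
EGFP and pdgfrb levels in CPM by class and library on log axes, with exact Poisson 95% intervals and open triangles at the upper bound where no UMI was seen. Classes with under 10 cells in a library are left out. EGFP is highest in mural-like cells of each library that has them, and fibroblast-like cells of the wildtype and mutant libraries hold 678 and 702 CPM.

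The second comparison asks what changes in the sorted cells of older fish 7 days after amputation, when the ventricle is regenerating. Fibroblast-like and epicardium-like cells of the injured heart held more transcripts of genes that heart regeneration is known to switch on: 16 of 19 measured members of the regeneration list were higher and 0 lower, with a median log2 ratio of 2.12 (1.16 to 3.71), above all 10000 random lists. The members with most UMIs were fn1b, fibronectin (3.96-fold higher, 1.99, 1.92 to 2.06), mdka, the growth factor midkine (6.08-fold, 2.60, 2.52 to 2.69), sparc (1.69-fold, 0.75, 0.69 to 0.81, but 0.37 and under 1.5-fold with TMM scaling) and hapln1a (2.63-fold, 1.39, 1.28 to 1.51). The shares of mural-like cells and of the pooled class differed within counting error. Mural-like cells were 0.949% of uninjured (19 of 2003, 0.572 to 1.48%) and 1.22% of injured cells (17 of 1393, 0.713 to 1.95%). Fibroblast-like and epicardium-like cells together were 16.8% (337 cells, 15.2 to 18.5%) and 17.6% (245 cells, 15.6 to 19.7%).

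The split of that pooled class into 2 clusters depended on the clustering. In the main one the epicardium-like cluster held 223 of the 337 uninjured cells and 129 of the 245 injured cells, and the fibroblast-like cluster 114 and 116. Of all kept cells, fibroblast-like cells were 5.69% (4.72 to 6.80%) in the uninjured and 8.33% (6.93 to 9.90%) in the injured library. With doublets kept, the epicardium-like class held 23 uninjured and 26 injured cells and the fibroblast-like class 317 and 219, and with the 18-month pair clustered alone these were 21 and 25, and 310 and 218. Thinned to 500 UMIs they were 221 and 124, and 134 and 130. In each main cluster alone, a split chosen after seeing the data, the regeneration list was still higher: 14 of 18 in the fibroblast-like cluster (median 1.96) and 14 of 16 in the epicardium-like cluster (2.14).

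Transcripts of pdgfrb were 2.32-fold more frequent in the injured library, with 414 against 211 UMIs, 61.8 and 26.7 CPM (log2 ratio 1.21, 0.97 to 1.46). They were also higher in fibroblast-like and epicardium-like cells (318 against 141 UMIs, 1.15, 0.86 to 1.45), while mural-like cells, with 81 and 56 UMIs, differed within counting error (0.48). With every cell thinned to 500 UMIs the ratio over all kept cells was 0.52. EGFP was higher as well, 180.6 against 93.0 CPM (0.96, 0.82 to 1.09), as were cxcl12b (206 against 90 UMIs, 1.44, 1.07 to 1.81) and Citrine (97 against 56, 1.03, 0.54 to 1.54), and fli1a had 350 and 290 UMIs (0.51, 0.28 to 0.74). In the injured library 1 cell held 73 of the 206 cxcl12b UMIs. Mural-like cells held 33 of the 206 injured and 14 of the 90 uninjured cxcl12b UMIs, so most lay outside that class. Fibroblast-like cells held 7 and 3 and epicardium-like cells 14 and 3.

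Among fibroblast-like and epicardium-like cells, the genes ranked highest after injury included 2 fibrillar collagen partners: col12a1a (803 against 33 UMIs, 24.0-fold, 4.59, 4.08 to 5.13) and col11a1b (93 UMIs in 29 cells against 0, at least 30.6-fold). The others were hbegfb, an EGF family growth factor (84 against 1 UMIs, in 8 cells), ccl44, a chemokine (106 against 2, in 9 cells), and the uncharacterised zmp:0000001268 (87 UMIs in 2 cells). Ranked lowest were krt91, a keratin (525 against 4540 UMIs, 8.76-fold lower, -3.13), il13ra2, a receptor of interleukin 13 (2 against 56, -4.83), and fabp10a, a fatty acid carrier (14 against 184, -3.74), which had their highest level in epicardium-like cells of the uninjured library. The remaining pair, rbp2a (179 of 180 UMIs) and si:ch211-217k17.10 (56 of 56), lay in 1 uninjured cell each. Chosen after their values were seen, 2 further members of the regeneration list were postnb, periostin (1173 against 81 UMIs, 3.84), and aldh1a2, which makes retinoic acid (2.12, 1.84 to 2.40).

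The matrix list was alike, with 15 of 16 members higher in these cells (median 1.39, 0.75 to 1.71): fn1b and sparc as above, col1a2 (2.78-fold, 1.47) and col1a1b (4882 against 2090 UMIs). The glycolysis list had 10 members higher and 1 lower of 14 (0.68, 0.22 to 1.24), with gapdhs at 0.86 and aldoaa at 0.57 (0.48 and 0.19 with TMM, under 1.5-fold). The interferon list had 6 higher of 8 (2.62) and the contractile list 7 of 11 (0.89), whereas the heat shock list had 2 higher and 4 lower of 15 (-0.50). Markers of cardiomyocytes were lower in these cells for 4 of 10 members (median -0.49). Fibroblast-like cells held 954761 of the 1759781 UMIs of the pooled class in the injured library and 517759 of 1736200 in the uninjured library. In the fibroblast-like cluster alone, a split chosen after seeing the data, 8 of 16 matrix genes were higher with TMM (median 0.59, pooled 1.01).

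Endocardium-like cells of the injured heart also held more matrix and regeneration transcripts. The regeneration list had 10 of 14 members higher (median 2.01, 0.48 to 4.43) and the matrix list 9 of 13 (1.16, 0.30 to 2.54). Members of the regeneration list included sparc (3.31-fold higher, 1.73), aldh1a2 (0.49, 0.31 to 0.66) and fstl1b, a secreted follistatin relative (0.48). In the matrix list the members with most UMIs were col1a2 (4.24-fold, 2.08), col1a1a (5.81-fold, 2.54) and col5a1 (3.48-fold, 1.80). A single cell weighed on col5a1, holding 278 of its 554 UMIs (without the top cells 1.09), and with every cell thinned to 500 UMIs its ratio turned to -0.012, while those of sparc, col1a2 and col1a1a became smaller. Markers of other classes were higher in these cells too: 10 of 12 fibroblast markers (median 1.52, without the top cells 1.08) and 6 of 9 members of the mural list, with 1 lower (1.08, without the top cells 0.06). Most fibroblast markers, among them col1a2, col1a1a and col5a1, are also in the matrix list, so their count is not a separate signal.

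The genes ranked highest in injured endocardium-like cells were thbs1b, thrombospondin (312 against 8 UMIs, 1 cell with 226), fn1a, fibronectin (63 against 0, 1 cell with 51), rgs5b (64 against 1, in 8 cells), and tagln and postnb, of which 1 cell held 211 of 212 and 211 of 211 UMIs. Ranked lowest were BX908782.2, which the files name by clone only (56 against 1751 UMIs, 30.5-fold lower, -4.93), steap4, a metal reductase (37 against 318, -3.07), cebpa, a transcription factor (15 against 98, -2.67), and si:ch211-181d7.3 (-2.71) and AL935186.1 (-2.75), which are not characterised under these names. EGFP was 187 against 123 CPM in these cells (0.61, 0.32 to 0.90), Citrine was 0 in both, and pdgfrb had 1 UMI against 0. EGFP UMIs were present in 54.5% of injured and 33.4% of uninjured endocardium-like cells and in 0 of 64 and 0 of 97 macrophage-like cells, with median depths of 4732 and 3760 UMIs against 6367 and 6032.

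Over all kept cells, cell cycle genes were higher in the injured library for 21 of 24 measured members (median 1.66, 0.93 to 2.30), with tubb2b, a tubulin, at 1.17 (with TMM 0.86), pcna, the replication clamp, at 0.64 (0.32, under 1.5-fold), and hmgb2a, a chromatin protein, at 0.34 (0.025). The interferon list had 6 of 8 higher (1.98, -0.23 to 3.61): isg15, a ubiquitin-like protein gene, was 5.26-fold higher (2.39). The transcription factor gene stat2 of the interferon pathway was at 1.19 and b2m, the light chain of class I molecules, at -0.18. The mural list had 11 of 16 higher (0.76), although its members with most UMIs did not differ by 1.5-fold: myl9b (0.01, with TMM scaling -0.31), rgs5b (0.00, -0.32) and myl9a (0.34, 0.03). The matrix list was higher for 18 of 18, the regeneration list for 18 of 22 (1.69), the contractile list for 10 of 14 with 1 lower (1.03), the PDGF list for 4 of 8 (0.79), the vessel signal list for 9 of 25 (0.56) and the complement list for 5 of 9 (0.63).

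Other lists over all kept cells were mixed. The inflammation list had 7 higher and 7 lower of 25 (0.05), the dissociation stress list 2 higher of 23 (0.08), the heat shock list 3 higher and 2 lower of 16 (-0.08), the TGF-beta and BMP list 4 higher of 11 (0.38) and the glycolysis list 2 higher and 2 lower of 20 (0.33). The ribosomal (0.02) and mitochondrial (-0.06) lists differed little, and the haemoglobin list was higher for 4 of 5 (1.23). Erythrocyte-like cells were 3.73% of injured and 0.949% of uninjured cells. The genes at the ends of the ranking mostly lay in single cells: ighv1-4, an antibody gene segment (901 of 959 UMIs in 1 injured cell), si:dkeyp-93a5.3 (301 UMIs in 4 cells), si:dkey-21e2.16, si:dkey-21e2.13 and si:dkey-21e2.10 (284, 126 and 203 UMIs in 1 cell each). On the lower side these were f13a1a.1, a clotting factor subunit (466 of 469 in 1 uninjured cell), si:ch211-217k17.10 (56 of 67) and snorc, a cartilage proteoglycan (77 of 101), likewise. More cells carried the other lower pair, BX908782.2 (154 against 1980 UMIs, -3.44) and csf3b, a myeloid growth factor (6 against 116, -4.03).

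The median log2 ratio of genes with at least 50 UMIs, again without mitochondrial, ribosomal protein and haemoglobin genes, was 0.30 over all kept cells. It was 0.36 in fibroblast-like and epicardium-like cells and 0.05 in endocardium-like cells. TMM scaling shifts all ratios by -0.32, -0.38 and -0.10. With it pdgfrb was at 0.90 over all kept cells and the regeneration list at 1.74 in fibroblast-like and epicardium-like cells. There 11 of 16 matrix genes stayed higher, the glycolysis list went to 3 higher and 2 lower, the inflammation list, with 6 higher and 4 lower of 17 before, to 2 higher and 7 lower, and 56 of 86 ribosomal protein genes became lower. The heat shock list there went to 2 higher and 9 lower, and the contractile list to 5 higher and 1 lower. Over all kept cells the mural list had 7 of 16 higher, the contractile list 8 of 14 with 1 lower, the matrix list 15 of 18 and the cell cycle list 16 of 24. The PDGF list had 3 of 8 higher, the vessel signal list 6 of 25, the complement list 3 of 9 with 1 lower, and the TGF-beta and BMP list 1 higher and 1 lower of 11. The dissociation stress list had 1 higher and 4 lower of 23 and the heat shock list 3 higher and 6 lower of 16.

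**Figure D3:**
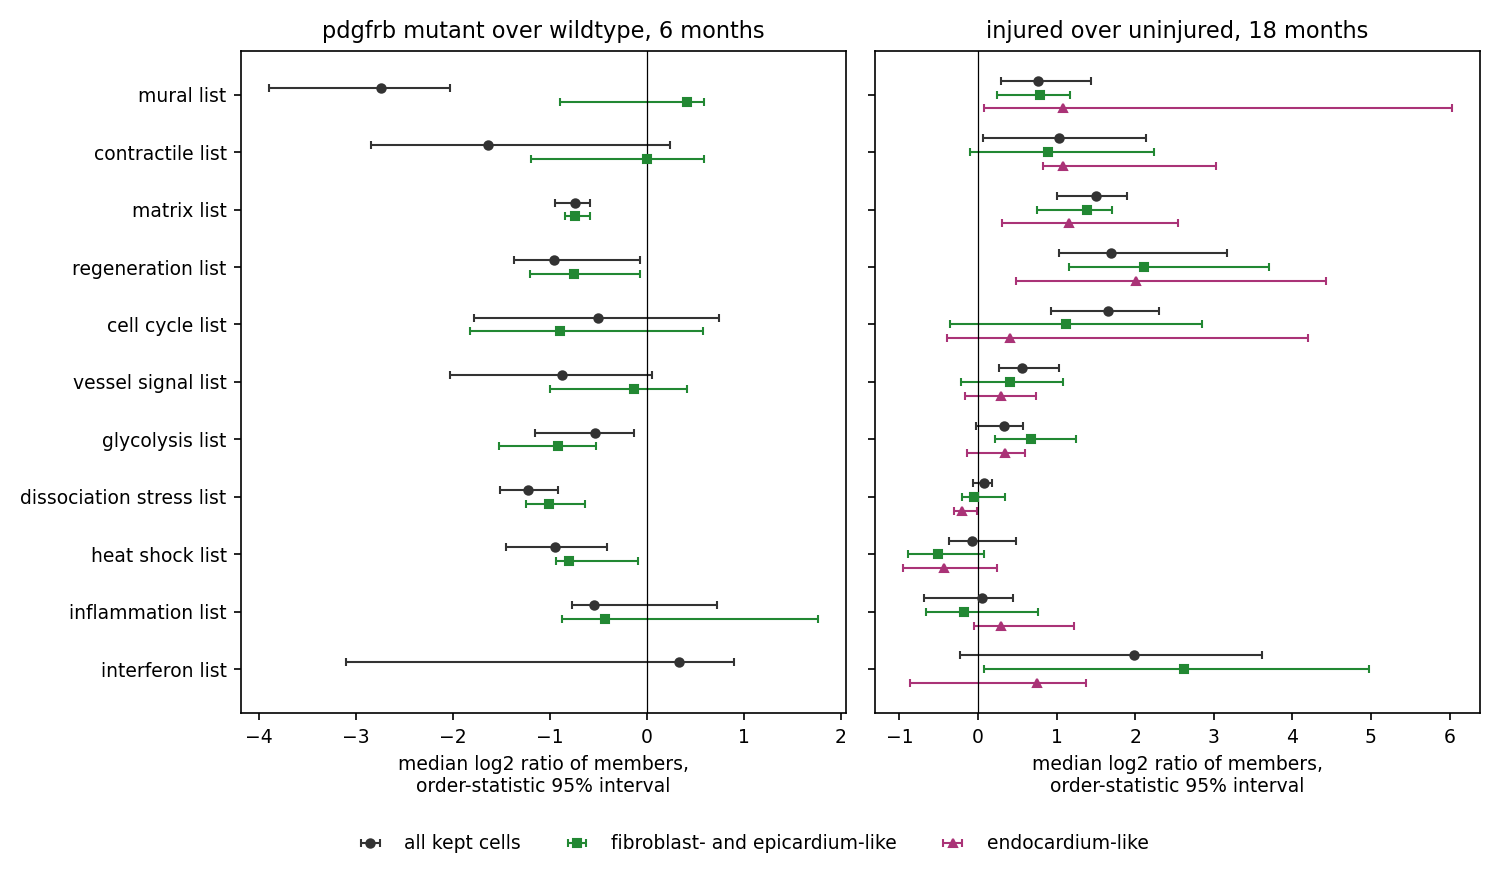
Median log2 ratio of the members of 11 fixed gene lists, with order-statistic 95% intervals (the full range for lists of under 6 members), for mutant over wildtype at 6 months and injured over uninjured at 18 months. Matrix and regeneration lists lie below 0 in the mutant comparison and above 0 in the injury comparison, in every population drawn.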

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

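Here, all tests but 2 were chosen only after the result was seen: the search for mural genes among barcodes left out, and the neighbours of psmb8a, were written before. Signals outside the comparisons met a rule fixed in advance. Citrine, read from cxcl12b, stood above its control library in cardiomyocyte-like cells: 22.65 CPM in the mutant against 12.2 CPM in wildtype, and 33.68 CPM in the injured against 14.6 CPM in the uninjured library, while cxcl12b itself had 0, 1, 2 and 2 UMIs in these cells of the wildtype, mutant, uninjured and injured libraries. Barcodes with over 90% mitochondrial UMIs, which the comparisons left out, made up 13.08% of wildtype and 9.91% of mutant barcodes, and 55.63% of uninjured and 44.3% of injured barcodes.

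Mural-like cells, which carry pdgfrb, kcne4 and rgs5b, were not found in the mutant library. At least 2 UMIs of 6 mural genes were in 33 of 1119 kept mutant cells, 31 fibroblast-like and 2 epicardium-like, and in wildtype in 30 and 3 cells of these classes and 91 of 92 mural-like cells. Over all kept cells 52 mutant cells held 521 rgs5b UMIs, 218 in fibroblast-like, 207 in epicardium-like and 81 in cardiomyocyte-like cells. Clustered without the mural markers, all 92 wildtype mural-like cells fell in 1 cluster that held 0 of 1119 mutant cells, which bounds their share at 0.3291%. The gap thus does not rest on those markers alone. Other genes high in mural-like cells were not left out, so mutant mural cells that changed these too could lie in other clusters. Removal by the filter on detected genes alone was hardly tested: asking for 100 genes raised the mutant cells from 1119 to 1126 only. Of these 1126 cells 0 were mural-like (upper bound 0.3271%). Removal by the filter on mitochondrial UMIs alone is argued against: without it 0 of 1242 mutant cells were mural-like (upper bound 0.297%). Removal by the cell filters together cannot be told apart from a loss, since 1 of 385 left-out mutant barcodes (0.2597%, up to 1.44%) and 2 of 391 wildtype ones (0.512%) held at least 2 UMIs of 6 mural genes, and 254 of the 385 failed both filters. A sort or dissociation that left out cells with much EGFP cannot be told apart from a loss of the cells: 0 mutant cells reached the EGFP level of 4829.3 CPM that 70 wildtype cells did, while EGFP in fibroblast-like and epicardium-like cells was equal (0.00). A lack of mural cells in mutant hearts may be the cause, as a hypothesis, and stays untested with 1 library per genotype.

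In endocardium-like cells of the 18-month libraries EGFP had 413 UMIs and pdgfrb 1. Free EGFP RNA is argued against by macrophage-like cells, which had 0 EGFP UMIs (upper bound 3.321 CPM) against 154.7 CPM in endocardium-like cells. Doublets with mural-like, fibroblast-like or epicardium-like cells would have brought 138.7 pdgfrb UMIs, and the upper bound of the 1 seen is 5.57. Citrine transcripts counted as EGFP would have come with 2460.0 Citrine UMIs, and 0 were seen. No biological explanation was tested.

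The proteasome genes psmb8a, psmb9a, psmb12 and psmb13a, subunits of the form that makes antigen peptides, were higher in the injured library in 4 classes, found by a scan after the values were seen. Median log2 ratios were 2.90 in cardiomyocyte-like, 2.91 in fibroblast-like and epicardium-like, 2.89 in endocardium-like and 2.55 in macrophage-like cells, while in the last 3 of these the class I gene mhc1uka was higher (2.33, 1.39 and 1.85) and mhc1uba lower (-4.93, -2.45 and -3.03). The peptide carrier gene tap2a was at least 2.57 higher in fibroblast-like and epicardium-like cells and 3.03 in endocardium-like cells. Different forms of the chromosome region in the fish of the 2 libraries were predicted to change its other genes more than most regions. This was not met: the 20 nearest measured genes of other families changed less than most windows (percentile 11.06, median size 0.296 against 0.418). Genes named psmb, mhc1, tap1, tap2 or tapbp were left out of every window, so the test says nothing about them. Forms that differ need not change most neighbours, so the low median cannot exclude them. Different forms of the psmb and class I genes alone cannot be told apart from an effect of injury: the medians over these 3 classes were 1.85 for mhc1uka and -3.03 for mhc1uba, and each group is 1 library. An interferon response cannot be told apart from other causes, because the interferon list in macrophage-like cells had a median of -0.47 over 5 members that went both ways. In fibroblast-like and epicardium-like cells it was higher for 6 of 8 members (2.62), in endocardium-like cells for 4 of 7 (0.74, with TMM 3 higher and 2 lower) and in cardiomyocyte-like cells for 1 of 3 (0.65). Injury, which the design names, stays open and untested.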

How the results depend on the processing

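Chosen only after the result was seen were the tests without the highest 5% of doublet scores, without the mural markers, without each gene's top cells, with shares without cardiomyocyte-like and erythrocyte-like cells, with each cluster of the pooled class alone, and of the mural list over all kept cells. No paired analysis was possible because each group has 1 library and the groups share only the replicate number 1, so there was no test to pair. The mural list in mural-like cells has no value under any setting, since the mutant library has 0 such cells, and its median over all kept cells stood in.

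With shares taken without cardiomyocyte-like and erythrocyte-like cells, mutant minus wildtype was -39.66 points for mural-like and 36.0 points for fibroblast-like and epicardium-like cells. The pdgfrb ratio of injured over uninjured moved to 0.90 with TMM, 0.89 with DESeq2 size factors, 0.88 as the mean over cells and 0.52 thinned. In endocardium-like cells, thinning turned col5a1 to -0.012 and fli1a to -0.076. In mutant cardiomyocyte-like cells gapdh turned to -0.026 with TMM and -0.040 with DESeq2. The cause of these changes was not tested. A value counted as kept if it lay inside the interval of the main value. The mural share, mutant minus wildtype, kept its size in 10 of 11 settings, the pdgfrb ratio of mutant over wildtype in 10 of 10, the mural list in 12 of 12 and the regeneration list in 16 of 16 (1.69 to 2.23). For both lists that interval spans the spread between members, far wider than the scaling shifts, so scaling could hardly move them. Counting each list or gene once per setting, 39 of 914 values of the other list medians moved (20 smaller, 19 larger), and of 1633 values of named genes 341 moved (255 smaller, 86 larger) and 4 reversed. Of named genes, thinning moved 84 of 135 (13 more had no value), TMM 54 of 148, DESeq2 55 of 148 and the mean over cells 51 of 148, against 8, 5 and 9 with 400 genes, doublets kept or no mitochondrial filter.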

Other observations

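Cardiomyocyte-like and macrophage-like cells lie outside the rule for named genes. They were ranked in the same way, and these tests were chosen only after the result was seen. In injured cardiomyocyte-like cells anxa2a, a membrane-binding annexin, was the gene ranked highest (1290 against 61 UMIs, in 138 and 35 cells, log2 ratio 4.94). Next came nppal (87 against 1 UMIs), ankrd1a, a stress-responsive ankyrin repeat gene (106 against 2, 48 in 1 cell), the small heat shock gene hspb9 (170 against 5) and BX323861.3 (52 against 1). Ranked lowest were mt2, a metallothionein (6 against 123, -3.82), znf326 (3 against 52, -3.57), rbp4, a retinol carrier (14 against 186, of which 152 in 1 cell), gpib, a glycolysis enzyme (77 against 457, -2.03) and lxn, a peptidase inhibitor (88 against 504, -1.98). Dissociation stress genes were higher for 13 of 20 (median 0.71, with TMM 8 of 20), with fosab at 0.88, jun at 0.54 and atf3 at 0.09 (0.56, 0.22 and -0.23 with TMM, each under 1.5-fold). The median of genes with at least 50 UMIs in these cells, without mitochondrial, ribosomal protein and haemoglobin genes, was 0.22.

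In mutant cardiomyocyte-like cells lxn (316 against 28 UMIs, 2.96) and mt2 (100 against 5, 3.79) were higher, beside zgc:152791 (62 against 1), si:dkey-188i13.10 (114 against 7, 3.49) and her4.1 (52 against 3). Lower were tcima (72 against 922, in 32 and 199 cells), zgc:86709 (-2.84), mibp (29 against 120), ndrg3a (49 against 184) and CT573476.1 (11 against 46). Of the glycolysis list, 7 of 17 were lower (median -0.52, with TMM 9 of 17), while the members with most UMIs, gapdh (0.07, with TMM -0.03), aldoaa (-0.42) and tpi1b (-0.52, with TMM -0.62), were under 1.5-fold by the main scaling. Of the clusters of this class, cluster 4, with zgc:86709 as its leading gene, held 6.23% of wildtype and 0.894% of mutant cells, cluster 6 held 13.6% and 19.1%, and cluster 9 held 10.35% and 16.1%. At resolution 0.5 the cluster led by zgc:86709 held 107 wildtype and 64 mutant cells. Cluster 1 held 17.8% of uninjured and 12.7% of injured cells, and cluster 13 held 0.649% and 2.37%.

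In macrophage-like cells (64 injured, 97 uninjured) the inflammation list had 7 members lower and 3 higher of 23 after injury (median -0.40), with the chemokine gene ccl35.1 at -1.09, ccl34a.4 at 0.37 and nfkbiaa, an inhibitor of NF-kappa-B, at -0.54. Markers of other classes were lower in these cells too: 3 of 4 neutrophil markers (-1.45, without the top cells -0.66) and 5 of 6 cardiomyocyte markers (-2.61, without the top cells -1.38). Marker lists over all kept cells had medians, mutant over wildtype, of -0.73 for fibroblast, 0.37 for epicardium, 0.07 for cardiomyocyte and 1.48 for macrophage markers, the last 0.95 without the top cells. For injured over uninjured they were 1.54 for fibroblast, 0.36 for epicardium, 0.15 for endothelium, 0.02 for cardiomyocyte, -0.14 for macrophage, 0.01 for neutrophil, 0.29 for lymphocyte, 2.03 for erythrocyte, 1.34 for thrombocyte and 0.56 for glia and neuron markers. Most fibroblast markers are also members of the matrix list, so their medians largely restate it.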
